A study of Homo sapiens with 2 samples.

How the data were processed

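RNA-seq was compared between 1 vector control library and 1 SCRN1 knockout library of HepG2 cells, grouped by the genotype given in the labels. Per the labels' protocols, total RNA was purified, treated with DNase and separated to mRNA before library construction. The submitters' processing notes name bcl2fastq 2.19, HISAT2 2.0.4, StringTie 1.3.0 and the build GRCh38. The deposited table lists only mouse genes, and the mouse build, the counting tool and the strand setting are not given in the sources used here.

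The authors deposited raw counts per gene for both libraries, as whole numbers that sum to 178421 and 163644. The deposited FPKM columns, per the file headers, hold fragment counts normalized for gene length and library size, and a second pair of columns repeats them. The deposited log2 fold change is the log2 of vector FPKM over knockout FPKM, the reverse of the direction used here. The authors' p-value and adjusted p columns compare 1 library with 1, and the adjusted p equals the Benjamini-Hochberg value over the listed genes to within 3e-15. No listed gene had fewer than 2 counts over both libraries, and the library totals implied by the deposited FPKM values are 179141 and 164271, so 720 and 627 counts lie outside the listed genes.

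Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3). For each gene the ratio of the knockout to the vector library was computed with its exact conditional binomial (Clopper-Pearson) interval at 95%. Genes with a summed count of at least 20 were called higher or lower when the ratio was at least 2 or at most 0.5 and the interval excluded 1. Reads are not independent molecules, so intervals and floors cover counting error only. On the log2 scale 0.5 was added to each count, and a fold against a count of 0 was taken against 3 counts as a lower bound. The quasi-likelihood test was not run, since 1 library per group leaves no residual spread. The edgeR exact test was run only with assumed coefficients of variation, as a description of what each assumption gives.

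The rule for named genes was fixed with the lists. It takes the secernin genes, the 15 genes each way with at least 100 counts and the interval bound farthest from equality, up to 4 called members of each list, 6 hepatocyte and reference genes, and the 2 most abundant members of a list that did not differ. The most abundant genes of the table, Zeb1, Zeb2, Vim, Psmb7, Psmd14, Rpl7 and Fetub were named after their values were seen. So were Lyz2, Ftl1, mt-Rnr1, mt-Rnr2, mt-Nd1, mt-Nd4 and mt-Atp6. Some genes that the rule takes are not reported here. A list's median log2 ratio over members with at least 20 counts was placed among 10000 random lists matched on mean expression in 20 bins, for lists of at least 3 such genes. Gene symbols were matched to human symbols by upper-casing, which matched 2794 of 2992 protein-coding symbols (93.4%) and is not a formal ortholog table.

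The rule was tested on simulated data drawn from the real means and library sizes. Changes of 2.5-fold were recovered for 80.4% of changed genes and of 4-fold for 97.4% with counting error alone, and for 68.2% and 94.1% with a biological coefficient of variation of 0.2. The interval held the true ratio for 96.5% of genes with counting error alone and for 76.1% with 0.2. Alternatives covered the scaling (library totals, DESeq2 1.42.0 size factors, upper quartile), the count filter, the fold and an assumed spread between cultures. The DESeq2 size factors (median of ratios) came out equal for both libraries, so that setting left the counts unscaled. FPKM values were used only for the implied totals. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.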

Results

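RNA was sequenced from HepG2 cells, a human hepatocellular carcinoma line, with SCRN1 (secernin 1) knocked out by CRISPR-Cas9 and from HepG2 cells carrying a vector control. There was 1 library per group, so no difference below has a replicate check, and every interval is a 95% exact interval that covers counting error only. The table analysed here lists 3764 genes, all with mouse Ensembl identifiers, mouse gene symbols and mouse positions, although both libraries are labelled human and the submitters' processing notes name the human build GRCh38. The total count was 178421 in the vector library and 163644 in the knockout library, and the median gene had 11 counts over both. A count of 0 allows up to 16.8 CPM in the vector library and 18.3 CPM in the knockout library, taking 3 counts as the floor.

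The first comparison asked whether the knocked-out gene differed between the libraries. Scrn1, Scrn2 and Scrn3 were not among the genes listed in the table analysed here, so the labels could not be checked against the targeted gene. In the human annotation GENCODE 29, on GRCh38, SCRN1 lies on chromosome 7 from position 29920103 to 29990289. Alb, Apoa1, Afp and Hnf4a, which mark hepatocytes and HepG2 cells, were not listed either, nor was Gapdh. Actb (beta-actin) had 16 counts in the vector library and 7 in the knockout library, a ratio of 0.484 (0.168 to 1.24), which was not distinguishable from equality at this depth. The 3 genes with the most counts were Hnrnpa2b1, Eif4g2 and Pabpc1. Hnrnpa2b1 had 5045 counts in the vector library and 5377 in the knockout library, Eif4g2 had 4029 and 3545, and Pabpc1 had 4016 and 3251.

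The second comparison asked which genes differed between the knockout and vector libraries. Tmsb4x, which encodes the actin-monomer binding protein thymosin beta-4, had 5 counts in the vector library and 665 in the knockout library, a ratio of 147 (62.8 to 455). Psmc1, an ATPase subunit of the 26S proteasome, had 0 and 149 counts and was at least 55.0-fold higher in the knockout library against the floor of 3 counts, with an interval that starts at 44.1. Eif3m, a subunit of translation initiation factor 3, had 132 and 0 counts and was at least 39.8-fold lower against that floor, with an interval that starts at 31.9. Spp1, which encodes the secreted phosphoprotein osteopontin, had 35 and 2 counts and was 15.8-fold lower in the knockout library (4.06 to 136).

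Of 1588 genes with at least 20 counts over both libraries, 53 were higher and 62 lower in the knockout library by at least 2-fold with an interval that excluded equality. These 115 genes were 7.24% of those compared, and 1204 genes (75.8%) lay within 1.5-fold. With median-of-ratios scaling, which shifted every log2 ratio by -0.15, the split was 42 higher and 89 lower. That setting gave both libraries the same effective total (170873), so it made no correction for their different depths. It left the median log2 ratio of the compared genes at -0.12, against 0.03 with TMM. Its values below are therefore those of unscaled counts. A test on the reads of 2 libraries compares those libraries, not the conditions. In simulated libraries of the same depth, in which some genes were changed, the rule called 1.07% of the unchanged genes from counting error alone, 1.99% with a biological coefficient of variation of 0.1 and 5.84% with 0.2. With a coefficient of 0.4 it called 24.3%. Over 1588 genes these shares come to 17.0, 31.6, 92.7 and 386. The simulation drew each gene independently and held no error in assigning reads to genes. These numbers are therefore not estimates of how many of the 115 calls are false. Among 343 genes with at least 200 counts, the robust SD of the log2 ratio between the libraries was 0.22, where counting error gives 0.15.

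Genes with no count in 1 of the libraries were common among the sparsely counted. Of the 3764 listed genes, 478 had no count in the knockout library and 220 had none in the vector library. Among the 115 called genes, 10 were missing from the knockout library and 11 from the vector library.

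**Figure D1:**
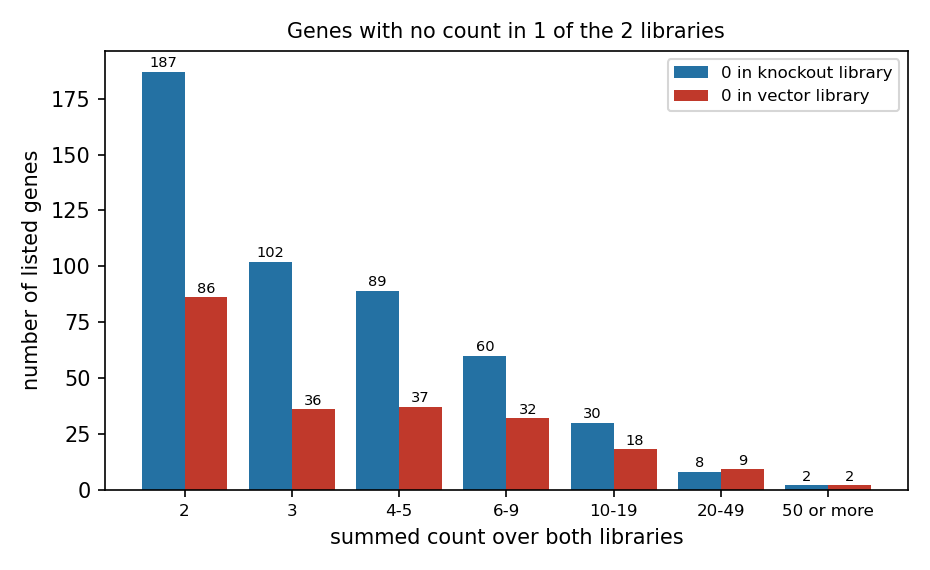
Number of listed genes with no count in the knockout library (blue) or in the vector library (red), by summed count over both libraries. With 2 counts in all, 187 genes were missing from the knockout library and 86 from the vector library, and with 20 to 49 counts the numbers were 8 and 9.

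**Figure D2:**
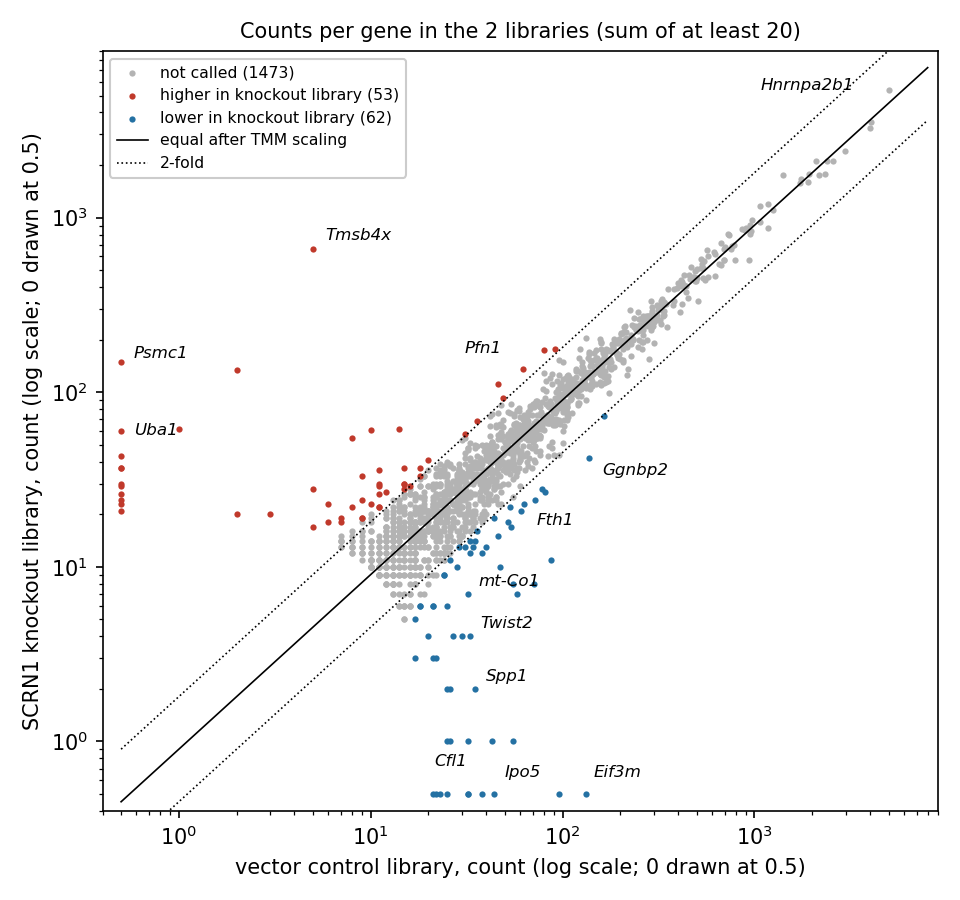
Counts per gene in the vector library (x axis) and the knockout library (y axis), both on log scales with 0 drawn at 0.5, for the 1588 genes with at least 20 counts over both; the solid line marks equality after TMM scaling and the dotted lines 2-fold. The 53 genes higher in the knockout library are red, the 62 lower are blue, and Tmsb4x and Psmc1 lie farthest above the line.

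Among the abundant named genes, with at least 100 counts, 8 of the 15 ranked as most clearly higher in the knockout library passed the 2-fold rule. Besides Tmsb4x and Psmc1, Pfn1 (profilin 1, an actin-binding protein) had 62 counts in the vector library and 135 in the knockout library and was 2.41-fold higher (1.77 to 3.31). Zbtb26, a zinc finger gene, was 2.41-fold higher (1.84 to 3.18), with 80 and 174 counts. The RNA-binding protein gene Rbm12 was 2.69-fold higher (1.90 to 3.89), and Rn7s2, a 7SL RNA of the signal recognition particle, was 2.16-fold higher (1.67 to 2.82). The ubiquitin ligase gene Wwp1 had a ratio of 2.10 (1.47 to 3.03). With median-of-ratios scaling 5 of the 15 passed, and Rn7s2 (1.96) and Wwp1 (1.90) were among those that no longer did. The named genes of this group that did not reach 2-fold ranged from Rmnd5a at 1.96 (1.36 to 2.85) to Hnrnpu at 1.38 (1.286 to 1.481), with Wac, Dmd, Dcun1d1, Sgms1 and Itpr1 between them.

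Of the 15 abundant genes ranked as most clearly lower in the knockout library, 5 passed the 2-fold rule. Ggnbp2 had 138 counts in the vector library and 42 in the knockout library and was 2.97-fold lower (2.09 to 4.30). Tardbp, which encodes the RNA-binding protein TDP-43, was 2.71-fold lower (1.73 to 4.36), and Fyn, a Src-family tyrosine kinase gene, was 2.52-fold lower (1.62 to 4.03). Rbm14, a gene of an RNA-binding coactivator, was 2.03-fold lower (1.53 to 2.71), and it overlaps the listed gene Gm21992, which had 46 and 15 counts. Nfat5, Psmd11, Nucks1, Cpeb2, Ipo7, Setd5, Ywhae, Rps6ka3 and Nipbl did not reach 2-fold, with vector-over-knockout ratios from 1.97 (1.37 to 2.88) for Nfat5 to 1.39 (1.21 to 1.60) for Nipbl. With median-of-ratios scaling 7 of the 15 passed, with Nfat5 (0.458) and Psmd11 (0.489) added, and with library totals 6 passed, with Nfat5 (0.4997) added.

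On mouse coordinates, whose build is not given in the sources used here, Tmsb4x lies on chromosome X from 167207093 to 167209315, Psmc1 on chromosome 12 from 100110154 to 100123405 and Eif3m on chromosome 2 from 104999656 to 105017080. All 3 are annotated as protein-coding. The listed genes included 683 processed pseudogenes, which held 10.9% of the counts in the vector library and 11.5% in the knockout library. How reads shared between a gene and its copies were counted is not given in the sources used here, so the values of Tmsb4x, Pfn1, Cfl1, Actb, Fth1 and Ywhae, which have many copies, are uncertain. Rbm12 overlaps Gm28036 (7 and 0 counts) and Cpne1 (0 and 2 counts), and Rn7s2 overlaps Gm47299 (13 and 1 counts).

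The third comparison asked whether groups of genes moved together. Of the 52 gene lists fixed before the data were examined, with 1034 genes, 44 had at least 1 listed gene, and 86 of their genes had at least 20 counts. Of these 86 genes, 8 differed by the 2-fold rule, 3 higher and 5 lower in the knockout library. In the actin cytoskeleton and migration list, 13 genes were compared: Tmsb4x and Pfn1 were higher, Cfl1 (cofilin 1, an actin-severing protein) was 22.6-fold lower (3.70 to 927) with 25 and 1 counts, and 10 did not pass. The median log2 ratio of this list was -0.09 and its mean 0.16, so the signs differed. In the proteasome list 9 genes were compared and Psmc1 alone was higher. Its median was -0.01 and its mean 0.92, Psmb7 had 248 and 223 counts, and Psmd14 had 201 and 217.

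Among genes lower in the knockout library, Fth1, the ferritin heavy chain gene, had 63 and 23 counts and was 2.48-fold lower (1.51 to 4.18). By symbol match, Fth1 was the only compared member of the NRF2 and antioxidant list and 1 of 3 in the ferroptosis and iron list. Both lists hold FTL, which does not match the mouse symbol Ftl1, so their values leave out Ftl1. That ferritin light chain gene had 25 and 6 counts and was also called lower, at a ratio of 0.266 (0.0891 to 0.663). Twist2, a transcription factor gene of mesenchymal cells, had 33 and 4 counts and was 7.45-fold lower (2.65 to 28.97), while Zeb1 (0.801, 0.434 to 1.45), Zeb2 (0.571, 0.292 to 1.08) and Vim (1.38, 0.604 to 3.24), the other compared members of the mesenchymal list, did not pass. Spp1 was the only compared member of the extracellular matrix list and 1 of 2 in the cholangiocyte list. The mitochondrially encoded gene mt-Co1, a cytochrome oxidase subunit gene, had 32 and 7 counts and was 4.13-fold lower (1.79 to 11.1).

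For the 12 lists with at least 3 compared genes, the median log2 ratio was set against 10000 random lists of the same size and mean expression, and 0 lay outside the central 95%, where 0.6 would by chance. The mesenchymal transition list came closest, with a median of -0.55 at percentile 7.08. Exocytosis and vesicle fusion genes, which include Rab11a (292 and 284 counts) and Vamp7 (55 and 56), had a median of 0.14 at percentile 76.0. Glycolysis had a median of 0.25 (percentile 89.9), with Pgam1 at 1.16 (0.960 to 1.41) and Pkm at 1.61 (0.994 to 2.63). The TGF-beta target list had a median of 0.36 (percentile 88.0), with Smad7 at 1.88 (1.09 to 3.29) and Smad6 at 1.62 (0.758 to 3.56). The G1/S and DNA replication list had a median of -0.17 (percentile 12.9), with Mcm4 at 0.891 (0.717 to 1.11) and Pola1 at 0.795 (0.575 to 1.095).

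The other tested lists were heat shock (median 0.28, percentile 83.9; Hsph1 41 and 43 counts, Chordc1 24 and 27), YAP and TAZ targets (0.13, percentile 66.0; Crim1 87 and 86, Tead1 75 and 74), and autophagy and lysosome (-0.02, percentile 33.8; Gabarap 438 and 404, Gabarapl1 126 and 117). Reference housekeeping genes had a median of 0.07 (percentile 58.8), ferroptosis and iron handling -0.24 (percentile 16.9), the proteasome list percentile 43.8 and the actin list percentile 11.7. With median-of-ratios scaling the medians of the exocytosis, YAP and TAZ, and housekeeping lists changed sign, to -0.01, -0.02 and -0.08.

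Pooled counts per list were compared as well, a comparison chosen after the data were seen. Of the 44 lists, 11 had an interval below equality and 2 above it. With median-of-ratios scaling these were 13, with the G1/S (0.811, 0.695 to 0.946) and autophagy (0.844, 0.755 to 0.943) lists added, and 1. The 9 listed mitochondrially encoded genes had 77 counts in the vector library and 18 in the knockout library, 3.87-fold lower (2.29 to 6.86), and 3.70-fold lower (1.88 to 7.93) without mt-Co1. Among them, the rRNA genes mt-Rnr2 (7 and 7 counts) and mt-Rnr1 (1 and 1) were even, and only mt-Co1 had at least 20 counts. The 13 listed cytosolic ribosomal protein genes had 88 and 41 counts, 1.94-fold lower (1.32 to 2.88), and 1.76-fold lower (1.20 to 2.64) without Rpl7. Of the 11 lists, 9 had 2 or more listed genes, and these were the 2 that stayed below equality without the member of largest difference. Pooled ratios were not set against random lists. Most listed members of both had fewer than 10 counts. Over the whole table, such genes were more often at 0 in the knockout library (438) than in the vector library (191). The lower counts of those members therefore cannot be told apart from that general skew. Members with 10 or more counts, such as mt-Co1 (32 and 7) and mt-Rnr2, lie outside it. With 20 to 49 counts, 8 genes were at 0 in the knockout library and 9 in the vector library. How much of each pooled ratio comes from the skew was not tested. The actin list was 1.51-fold higher (1.41 to 1.61) and 1.02 (0.952 to 1.103) without Tmsb4x. The proteasome list was 1.20-fold higher (1.08 to 1.33) and 0.975 (0.876 to 1.09) without Psmc1, and 1.08 (0.980 to 1.20) with median-of-ratios scaling.

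**Figure D3:**
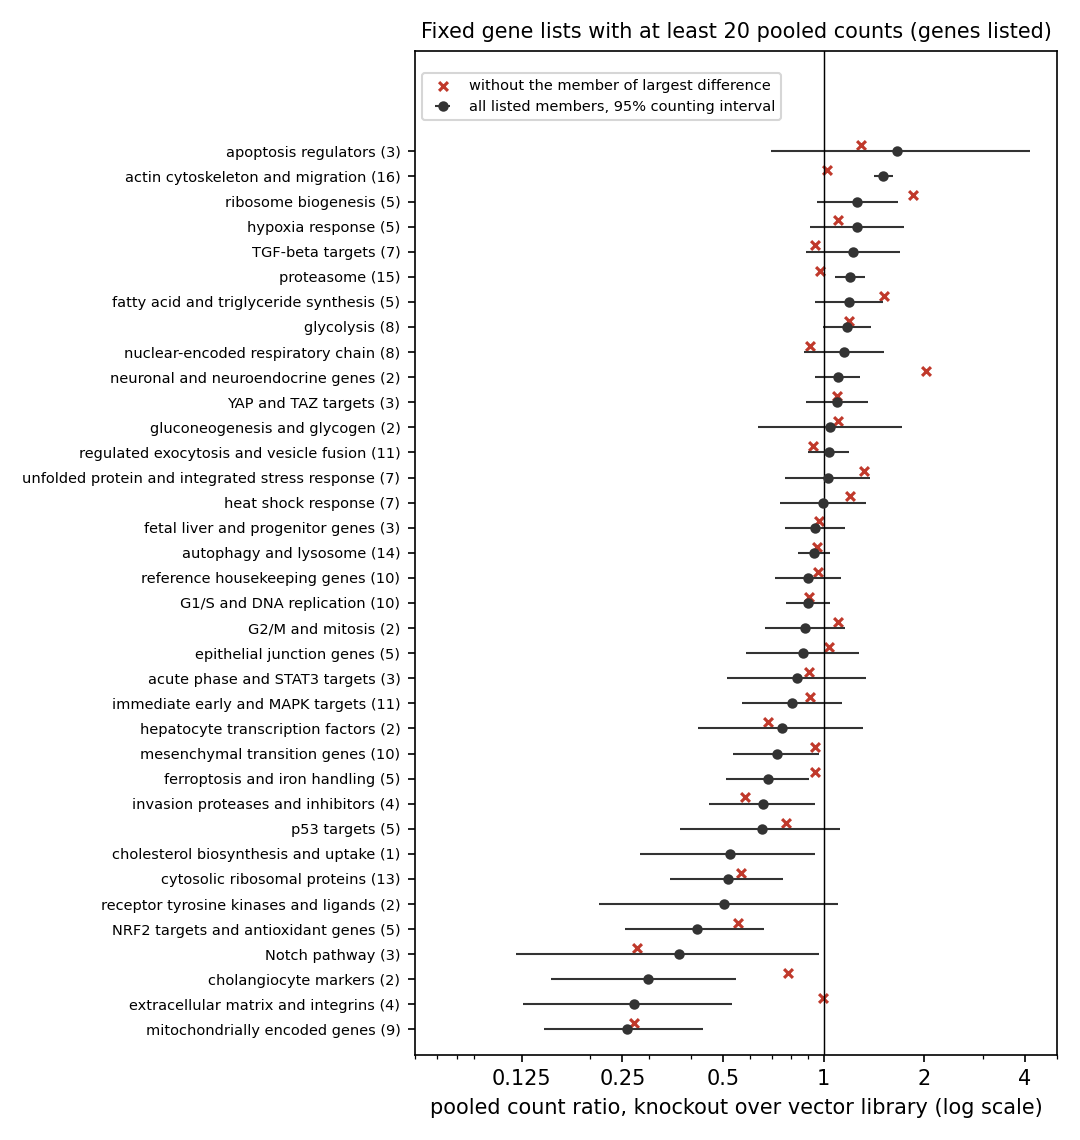
Pooled count ratio of each fixed gene list with at least 20 pooled counts, knockout over vector library on a log scale, with the 95% counting interval as a bar and the number of listed genes in brackets; crosses leave out the member of largest difference. The mitochondrially encoded genes (18 against 77 counts) lie lowest, and the actin list returns to 1.02 without Tmsb4x.

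Genes of hepatocyte function were sparsely listed. Of 30 plasma protein genes, 1 was listed, Fetub (fetuin B), with 16 counts in the vector library and 0 in the knockout library. No symbol of the complement and coagulation, metallothionein, interferon, replication-dependent histone, checkpoint ligand, endothelial or leukocyte lists matched a listed gene. Some human and mouse symbols differ, so a missing match does not show that a gene was absent. The leukocyte list holds LYZ, for example, and the mouse lysozyme gene Lyz2 was listed with 21 and 3 counts. Lyz2 was also called lower in the knockout library, at a ratio of 0.158 (0.0302 to 0.529).

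The fourth comparison was the authors' own test of the knockout against the vector library. The authors' deposited table called 101 genes at an adjusted p of 0.05, of which 41 were higher and 60 lower in the knockout library. Its log2 fold changes are vector over knockout, so that a gene marked up there is higher in the vector library. Psmc1 had an adjusted p of 1.53e-28 and Eif3m of 9.33e-25 in the authors' deposited table. Both methods called 64 genes in the same direction, 27 higher and 37 lower in the knockout library, while 51 genes were called by the 2-fold rule alone. Of the 101 genes called in the authors' deposited table, 37 had fewer than 20 counts and 57 had a count of 0 in 1 library. The p-values of the authors' deposited table were returned by the edgeR exact test with an assumed biological coefficient of variation of 0.1, to within 5.22e-15, so they rest on a spread that was not measured in these libraries.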

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

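The tests of depth and of transcript class were set down before their results were seen, while the pattern was noticed in the same data and the mitochondrially encoded genes were compared only after the result was seen.

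Genes below the count filter were more often missing from the knockout library. Among genes with fewer than 10 counts over both libraries, 438 had no count in the knockout library and 191 had none in the vector library, a ratio of 2.29. This stood out because these genes lie outside the comparisons of genes with at least 20 counts, where 10 genes had no count in the knockout library and 11 had none in the vector library. The lower depth of the knockout library did not account for it, since the ratio stayed at 2.015 over 100 draws (1.90 to 2.12) after thinning the vector library to the knockout total. A trace of mouse RNA in the vector library could add genes with few counts there, but the share missing from the knockout library was 69.6% (65.7 to 73.3) for protein-coding genes and 67.7% (48.6 to 83.3) for processed pseudogenes. That difference of 1.87 percentage points was too uncertain to decide. The 9 listed mitochondrially encoded genes, with 77 counts in the vector library and 18 in the knockout library, were 3.87-fold lower in the knockout library (2.29 to 6.86), and 3.70-fold lower (1.88 to 7.93) without mt-Co1. These genes are not separate support, since mt-Nd1 (6 and 0 counts), mt-Nd4 (5 and 0) and mt-Atp6 (4 and 0) are among the 438. The mitochondrial rRNA genes mt-Rnr2 (7 and 7) and mt-Rnr1 (1 and 1) were even. Such a trace or lower expression in the knockout cells could give the lower pooled count, so the trace stays open. Whether a trace also adds to genes called lower, such as Spp1, Fth1, Lyz2 and Cfl1, was not tested. Lower expression of the 438 genes in the knockout cells also stays open, since no second pair of libraries was analysed here. The choice of listed genes is a further limit. Of listed genes with 2 counts in all, 68.0% had 1 count in each library, where 49.9% was expected. Genes with both counts in 1 library were thus rarer than expected among those listed. The counts outside the listed genes, 720 in the vector library and 627 in the knockout library, cannot be assigned to genes. Whether the choice of listed genes shaped the ratio of 2.29 was not tested and stays open.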

How the results depend on the processing

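Dropping genes at 0, the FPKM-implied totals and the authors' test at larger spreads were chosen after seeing the data. None of the named genes that passed the 2-fold rule changed sign under another scaling. None could, since the largest shift of the log2 ratios was -0.15, with median-of-ratios scaling. With that scaling the 8 higher and 5 lower of the abundant named genes became 5 and 7, and with library totals 8 and 6. For the counts of 53 higher and 62 lower genes, removing the filter gave 128 and 167, at least 100 counts gave 9 and 5, 4-fold gave 22 and 31, and intervals excluding 2-fold gave 20 and 27. A 1.5-fold threshold gave 93 higher and 88 lower. The edgeR exact test gave 26 higher and 31 lower with an assumed coefficient of variation of 0.2, and 10 and 8 with 0.4. More genes were higher than lower at 1.5-fold, at 100 counts and with 0.4. The authors' 101 genes became 274 at a raw p of 0.05 with at least 2-fold and 64 at an adjusted p of 0.01, and 57 and 18 with a coefficient of 0.2 and 0.4. Filters and thresholds change these counts by construction.

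Of 63 alternative values of 12 list medians, 55 stayed within their counting interval, but 10 values of 6 lists changed sign. Of these, 4 did so under another scaling, which shifts every gene alike and says nothing about a list. The other 6, of 5 lists, came without a count filter or from means, and no direction is drawn from those lists. Without a count filter the medians were -0.70 (exocytosis), -0.082 (mesenchymal), -1.54 (autophagy) and -0.85 (housekeeping). That of ferroptosis turned to 0.15. Means were 0.92 (proteasome), -0.33 (autophagy), -0.22 (housekeeping) and 0.16 (actin), and median-of-ratios scaling gave -0.23 for actin. The proteasome mean includes Psmc1 at a log2 ratio of 8.37 and the actin mean includes Tmsb4x at 7.07, so the positive sign of each mean rests on that gene. Apart from these genes and from scaling, the cause was not tested. Of 153 scaled values of 51 named genes, 152 stayed within their counting interval, and Hnrnpu moved to 0.32. With median-of-ratios scaling Rab11a, Gabarap, Gabarapl1, Ywhaz, Crim1 and Tead1, which had not passed the 2-fold rule, changed sign. Depth limits most genes, since 1588 of 3764 had 20 counts. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. SCRN1 alternatives were not run, since the gene was not listed, and FPKM pseudocounts and filters did not apply to counts.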

Other observations

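The tests on the mouse gene list, on genes missing from 1 library and on the pathway terms were chosen only after the result was seen, and so were the genes named in the next paragraph. The chromosome test was set down before.

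Several called genes outside the rule for named genes were also far apart. Ipo5, which encodes a nuclear import receptor, had 96 counts in the vector library and 0 in the knockout library and was at least 28.9-fold lower against the floor of 3 counts, with an interval that starts at 23.1. Uba1, the main ubiquitin-activating enzyme gene, had 0 and 60 counts and was at least 22.1-fold higher against that floor, with an interval that starts at 17.5. Hif1a, the oxygen-regulated subunit of hypoxia-inducible factor, had 55 and 8 counts, a ratio of 0.161 (0.0662 to 0.340). Ftl1, the ferritin light chain gene, had 25 and 6 counts, a ratio of 0.266 (0.0891 to 0.663), beside the lower Fth1. It fell outside the rule only because its symbol differs from the FTL of the lists. The transcribed processed pseudogenes BC085271 (2 and 134 counts) and Gm14686 (1 and 62 counts) had ratios of 74.1 (20.1 to 619) and 68.6 (11.9 to 2753). Copb2, a coatomer subunit gene, had 10 and 61 counts, a ratio of 6.75 (3.43 to 14.8).

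Every listed gene was a mouse gene although the cells are labelled human. The table argues against RNA of mouse cells as the main source, since 0 of 51 mitochondrially encoded, ribosomal protein, Actb and Gapdh genes were among the 100 genes with the most counts. A candidate explanation is that human reads were counted over mouse genes, which would favour strongly conserved sequence. Of the proteasome genes 68.2% were listed, and of the plasma protein genes 3.33%. Cells that do not express hepatocyte genes would give this contrast too, so it cannot decide. The cytosolic ribosomal protein genes, 13 of 34 listed with 88 and 41 counts, were not weighed against this explanation. If human reads were counted over mouse genes, a count may depend on how well a human read matches the mouse gene as well as on expression. That the table belongs to other samples than the labels name was not tested and stays open, and every count and ratio here rests on it being theirs. No biological explanation of the mouse gene list was tested, since the design gives none.

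Of the 115 called genes, 21 had counts in 1 library and none in the other, including Psmc1, Eif3m and Ipo5. Counting error would give 0.000175 such genes among the 1588 compared. A shift of counts to an overlapping listed gene had a partner for 3 of the 21, Srcap with Gm42715 and Gm20521 with Pabpn1, so it could explain few of them. Absence of the transcript from the cells of 1 library, as a biological difference, stays open: 1 of the 21, Psmc1, was on the 5 fixed lists of genes that dividing cells need, and only 19 genes of those lists had at least 20 counts. Reads moved to gene copies elsewhere, listed or not, were not tested.

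As a hypothesis, a whole chromosome could differ in copy number between the cell populations. Among 20 human chromosomes with at least 20 genes, the largest median log2 ratio was 0.20, on chromosome 3 (87 genes, percentile 99.98 among random lists), and chromosome 9 had -0.12 at percentile 1.40. The bounds set down before left this undecided, since they asked for more than 0.32 or less than 0.2. Grouping by mouse chromosome, which the cells would not follow if they are human, gave as many extremes, chromosome 1 (0.16, percentile 99.7) and chromosome 15 (-0.09, percentile 1.69). Of the 12 listed genes within 5 Mb of human SCRN1, 4 had the 20 counts needed for a call, and 0 of those were called. Of 136 pathway terms given in the table with at least 10 compared genes, 1 lay outside the central 95% of random lists, where 6.8 would by chance. It was lysine degradation (13 genes, median -0.47, percentile 0.80).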
